A study of Mus musculus with 6 samples.

How the data were processed

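RNA was compared between 3 TRAP immunoprecipitates from cortex of a mouse line whose S100a10 regulatory sequence drives a tagged ribosomal protein and 3 samples of unbound whole cortex RNA. Per the labels' protocols, RNA was extracted with an acid phenol reagent, treated with DNase and column-cleaned, and 15 ng was amplified with a 2-cycle kit before hybridisation to Affymetrix arrays with a biotin label. Both groups received the same amount of RNA, so a difference in the amount of RNA per cell or per fraction is not measured. Amplification of this kind favours sequence near the poly(A) tail, so the position of a probe set in the transcript can change its value.

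The deposited values are intensities on a linear scale, which the authors obtained with GCRMA per the submitters' processing notes. GCRMA corrects each probe for background, quantile-normalises arrays and summarises the probes of a probe set by median polish, and its version is not given in the sources used here. Whether the 6 arrays were processed in 1 run or each group apart is also not stated. The series text mentions averaging over replicates, but the table used here holds 6 separate columns, and 0 columns were left unused. Quantile normalisation and the background step compress low values, so folds against a value near background are imprecise, and the median polish can give arrays of one run exactly the same value.

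Groups and replicate numbers were taken from the sample labels. Titles call the comparison RNA input, while descriptions and the series text call it unbound or flow-through, and the second reading was used. Of 45101 probe sets on the array, 64 are controls. The platform annotation gives 34958 probe sets 1 gene symbol, 932 several and 9211 none, controls included. Probe sets with none or several symbols were kept out of gene counts and lists. Of those with 1 symbol, 34754 matched a RefSeq gene by Entrez ID in the GRCm38.p6 table, which changed 0 symbols. That table was used for names only and no coordinates are given, since no genome build is named for the array.

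Values were analysed as log2 intensity without a pseudocount, since each value was above 0. A probe set was kept if a group mean reached 50 in at least 1 group, a limit taken from the series text, which can also be read as requiring it in both. This left 22591 probe sets. Each gene was represented by the probe set with the highest mean over the 6 arrays, giving 12070 genes. Among 5152 genes with several kept probe sets, 519 had probe sets called in opposite directions.

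Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, group as the only term, two-sided), with Benjamini-Hochberg adjustment over all 12070 genes and a threshold of 0.05. An adjusted p without another name is from this test or, for a list, from camera. A test against a 2-fold change used limma's treat. In 31 gene lists for cell types, RNA classes, receptors, channels and neuronal functions, fixed before the data were examined, the 29 with at least 3 tested members were tested with limma's camera at a correlation of 0.01, adjusted over those 29. Camera compares a list with all other genes, so its direction is relative to their shift. The red blood cell list had 0 members tested and the mitochondrially encoded list 1. By camera 6 lists were higher and 12 lower, and 0 passed with an estimated correlation, where the lowest adjusted p was 0.442.

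The genes named were chosen by a rule fixed before the data were examined. They are S100a10, the 12 called genes with the largest increase and the 12 with the largest decrease whose groups do not overlap and whose symbols are not clone names, up to 4 called members of each list with the largest folds, and every tested serotonin receptor. Genes named beyond this rule, among them list members that went against their list, abundant meningeal genes and examples of gene families, were chosen after their values were seen. Several listed genes have no probe set with a single symbol here and were not analysed here.

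The fit and the list tests were checked on simulated data. With 12070 simulated genes and 200 changed, 74% of 2-fold and 37% of 1.41-fold changes were recovered. Of the calls, 11.2% were genes that had not been changed. In the real data 69.0% of genes were called, so these rates need not hold there. By camera, a simulated list of shifted genes passed and a list of unshifted genes did not. With 3 samples against 3 the smallest two-sided permutation p is 0.1, so single genes were not tested by permutation. A further simulation summarised 2000 probe sets of 11 probes by median polish, once with each group apart and once with all 6 arrays together. Together it gave 0 calls by limma with 5% of unadjusted p under 0.05, and apart it gave 1053 calls.

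Deviations from the group means point to a pairing of the samples by replicate number. The correlation between same-numbered TRAP and unbound samples of their deviations from the group means, across genes, was 0.50, 0.46 and 0.37 for numbers 1, 2 and 3, and from -0.37 to -0.05 for different numbers. Deviations cancel within each group, so positive values for the same numbers tend to bring negative ones for different numbers. Genes are not independent replicates for this check. The labels do not state a pairing. The fit without the replicate block stayed the main one, as fixed before the data were examined.

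Alternatives covered the filter (none, both groups at 50, 1 group at 100), a pseudocount of 16, values under 50 raised to 50, quantile normalisation and median centring of the 6 arrays, the mean of a gene's probe sets, every probe set alone, eBayes with trend and robust options, the replicate block, each array left out in turn, camera with an estimated correlation, and fry. Added after the data were seen were the exclusion of probe sets of the _s_at and _x_at types, the exclusion of probe sets with repeated values, and the test against a 2-fold change. The probe set list recommended by the series text was not used here.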

Results

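Gene expression was measured on 6 Affymetrix arrays of 45101 probe sets, made from mouse cortex of a transgenic line in which regulatory sequence of S100a10 drives a tagged ribosomal protein. Translating ribosome affinity purification (TRAP) precipitates the tagged ribosomes together with the mRNA they carry. The TRAP group held 3 samples of precipitated RNA. The comparison group held 3 samples of whole cortex RNA, which sample titles call input and sample descriptions and the series text call unbound or flow-through; it is called unbound here. The line was backcrossed from FVB onto C57BL/6, no treatment was given, and the labels describe the samples as biological replicates without a number of animals, so p-values measure the spread between these samples, which may be partly technical. Median intensity over all probe sets was 31.6 ± 0.225 (SD, n = 3) on the TRAP arrays and 42.7 ± 0.366 (SD, n = 3) on the unbound arrays. The number of arrays limits the precision of every value.

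The comparison asks which transcripts distinguish S100a10-expressing cortical pyramidal cells from whole cortex. The series text states that the S100a10 line also labels some non-neuronal cells and recommends restricting the analysis to a published list of probe sets. That list was not used here, so each value below covers all labelled cells. Annotation of genomic position was not used, and genes are identified by the symbol of their probe set.

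S100a10, the driver gene, was higher in TRAP RNA, with an intensity of 14128 ± 1095 (SD, n = 3) against 2430 ± 451 (SD, n = 3) in unbound RNA. Its log2 fold change was 2.55 (SE 0.15), a 5.86-fold difference, with limma adjusted p = 8.3e-05. The 3 TRAP arrays ranged above all 3 unbound arrays. This value comes from a probe set of the type marked _x_at, which can cross-hybridise. Another probe set for the gene, of the unmarked type, gave 3816 ± 520 against 543 ± 112 (7.08-fold), and the third lay near background in both groups at 12.5 ± 0.221 and 16.3 ± 0.463.

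Genes encoding S100 proteins and annexins, of which annexin A2 is the partner of S100a10, were mostly higher in TRAP RNA. So were the markers of meningeal fibroblasts described below (list median 3.83). Pericyte and smooth muscle markers were higher in 6 of 8 tested, but the call of that list depended on the filter and the scaling. Of 15 tested members of the list, which also holds Ahnak and S100a10 itself, 14 were higher and 1, S100a16, was lower at a log2 fold change of -1.11. Anxa1 was 23.6-fold higher (log2 4.56, SE 0.18, adjusted p = 2.5e-05). Anxa2 reached 3126 ± 474 (SD, n = 3) against 141 ± 5.95 in unbound RNA (22.1-fold, adjusted p = 8.3e-06), and Anxa3 was 12.4-fold higher (adjusted p = 3.1e-05). The other Anxa2 probe sets lay under 50 in both groups and were not higher, with TRAP means of 6.53 and 31.0 against 6.69 and 39.0. The list median was a log2 fold change of 1.58 (camera adjusted p = 3.6e-06, and adjusted p = 0.442 with an estimated correlation). Counts adjusted over the list alone were also 14 higher and 1 lower.

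Across the 12070 genes tested, 880 were at least 2-fold higher and 1608 at least 2-fold lower in TRAP RNA at an adjusted p below the threshold. A test against a 2-fold change, chosen after the data were seen, called 547 genes higher and 792 lower. Without a size limit 2812 genes were higher and 5517 lower, 69.0% of those tested. The median log2 fold change of all genes was -0.21. After centring each array on its median the calls were 4105 higher and 4006 lower, so the share of calls in the higher direction moved from 33.8% to 50.6%, and it was 50.8% after quantile normalisation. These 2 scalings put the median of all genes near 0 (0.0054 and 0.0037), so a nearly even share was largely built in. The balance of 2-fold changes turned as well, to 1199 higher and 1112 lower after centring and 1256 and 1050 after quantile normalisation.

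Repeated values limit the spread between arrays as a measure of error. Between 17.9% and 21.6% of probe sets above the level minimum held exactly the same value on a given pair of arrays of one group, and 0% did on any pair from different groups. In 2000 simulated probe sets with no group difference, summarising each group apart gave identical values within a group for 40.6% and 1053 calls, of which 1 reached 2-fold and 0 passed the test against a 2-fold change. The simulation held more repeated values than these arrays do, but its median within-group SD of log2 values was 0.063 against 0.125 here. It covered median polish only, not background correction or quantile normalisation, so it does not limit the effect to calls below 2-fold. Whether the groups were summarised apart is not stated. If they were, calls below 2-fold, including those counted in the gene lists, are weaker evidence than their p-values state.

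The highest fold changes belonged to genes of several kinds. Foxd1, a forkhead transcription factor, rose from 129 ± 3.73 in unbound RNA to 6843 ± 403 (SD, n = 3) in TRAP RNA, a 53.1-fold difference (log2 5.73, SE 0.05, adjusted p = 4.9e-07). The forkhead gene Foxc2 was 44.5-fold higher, the homeobox gene Prrx2 52.4-fold, the glutathione transferase gene Gstm2 43.7-fold and the collagen gene Col1a2 37.7-fold. Tspan8, a tetraspanin, and Plscr2, a phospholipid scramblase, were 57.2-fold and 53.3-fold higher, Ecrg4 51.4-fold, Dapl1 49.8-fold and Cubn, an endocytic receptor, 46.0-fold. Several of these folds are set by unbound values near background. With values under 50 raised to 50, Tspan8 was 9.07-fold, Plscr2 18.4-fold, Prrx2 8.61-fold, Ecrg4 17.0-fold, Dapl1 25.2-fold, Cubn 6.04-fold, Gstm2 21.2-fold, Foxc2 41.1-fold and Col1a2 33.2-fold higher.

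Markers of meningeal fibroblasts, the cells of the brain's coverings, formed the list with the highest median. Of 15 tested members 14 were higher, each past the test against a 2-fold change, and Ccn3 was not called (log2 0.19, adjusted p = 0.28). Mgp, a matrix Gla protein, measured 7390 ± 828 (SD, n = 3) against 198 ± 30.5 (37.4-fold, adjusted p = 7.1e-06). Ogn was 34.4-fold higher (adjusted p = 1.8e-05) and Lum, the proteoglycan lumican, 36.6-fold, or 4.58-fold with values under 50 raised to 50. The list median was a log2 fold change of 3.83 (camera adjusted p = 1.2e-09, and adjusted p = 0.442 with an estimated correlation). The count adjusted over the list alone was also 14.

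Vascular and choroid plexus lists were mixed. Of 8 pericyte and smooth muscle genes, 6 were higher, with Myl9, a myosin light chain, 11.7-fold, Vtn, vitronectin, 11.1-fold, Tagln, an actin-binding protein, 10.4-fold and Atp13a5 5.85-fold (3.02-fold with values under 50 raised to 50). Rgs5 and Mylk of that list were lower, at log2 fold changes of -2.22 and -0.96. The list median was 2.14, or 1.66 with the raised values (camera adjusted p = 0.023, and adjusted p = 0.442 with an estimated correlation), but with no filter on low values it was -0.07 (adjusted p = 0.87). The call was also lost after centring and after quantile normalisation (adjusted p = 0.064 each) and when both group means had to reach 50 (adjusted p = 0.051). By fry, which tests against no change, the pericyte list did not pass (fry adjusted p = 0.53). Among 9 endothelial markers 4 were higher and 3 lower, with a median of 0.08 and a camera adjusted p = 0.11, and after centring 5 were higher and 1 lower. Itm2a was 8.74-fold and the transporter gene Abcb1a 3.79-fold higher, Abcg2 was 2.30-fold higher, and the transporter gene Slco1c1 was 5.94-fold lower. With the raised values Abcb1a was 2.84-fold higher and Slco1c1 4.99-fold lower. Of 5 choroid plexus and ependymal markers 3 were higher and Clic6 was lower at a log2 fold change of -0.43 (not called after quantile normalisation, -0.13), with a camera adjusted p = 0.11. The potassium channel gene Kcnj13 was 15.2-fold higher, Ccdc153 4.49-fold and Kl 2.66-fold, the last losing its call when values under 50 were raised to 50 (log2 0.12). Counts adjusted over the list alone equalled those over all genes for these 3 lists.

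**Figure D1:**
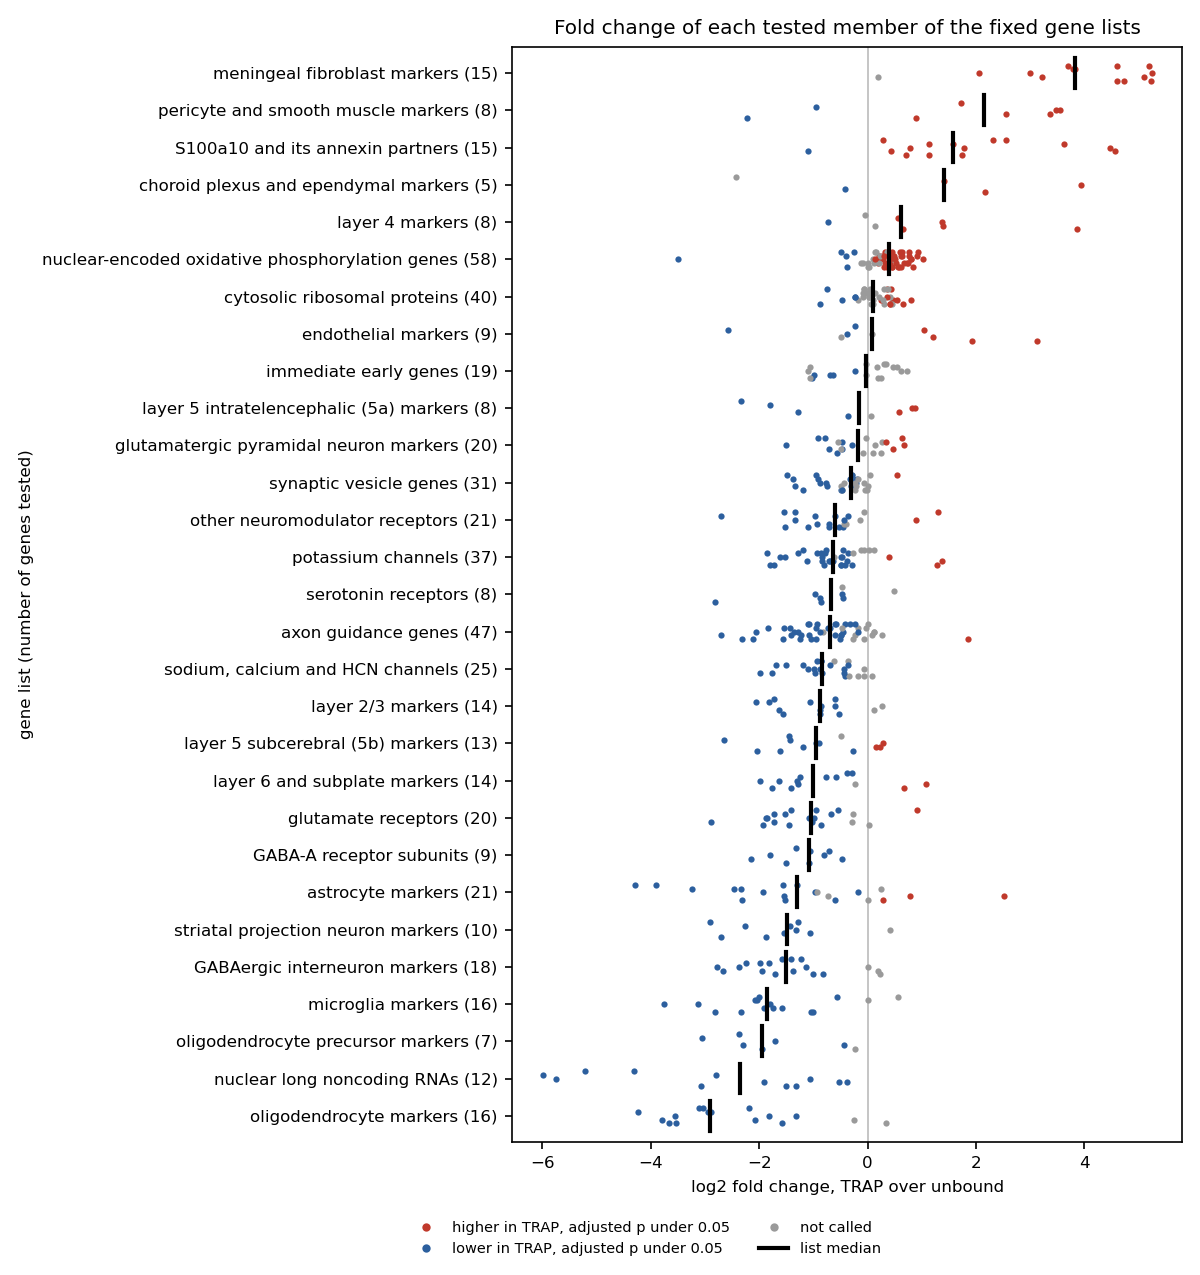
Log2 fold change, TRAP over unbound, of each tested gene in the 29 gene lists with at least 3 tested members. Each point is 1 gene, coloured by its limma call over all genes, and the bar is the list median. The meningeal fibroblast list has the highest median, 3.83, and the oligodendrocyte list the lowest, -2.92.

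Markers of oligodendrocytes, the myelin-forming cells, were lower in TRAP RNA. Of 16 tested members 14 were lower, and those 14 were at least 2-fold lower. Ermn fell from 5703 ± 791 (SD, n = 3) to 306 ± 83.1 (18.9-fold, adjusted p = 5.9e-05). Mog, a myelin glycoprotein, was 12.8-fold lower, the myelin gene Mal 11.8-fold and Myrf, a regulator of myelin genes, 13.8-fold, or 2.92-fold with values under 50 raised to 50. The list median was -2.92 (camera adjusted p = 0.0010). Of 7 precursor markers 6 were lower, among them the transcription factor genes Olig1 (8.32-fold) and Olig2 (5.18-fold) and the receptor gene Gpr17 (4.95-fold), but the list did not pass (median -1.95, camera adjusted p = 0.066). The precursor list passed after centring (adjusted p = 0.016) and without TRAP replicate 2 (adjusted p = 0.029). With an estimated correlation both lists had adjusted p = 0.442.

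Microglial markers were lower in 14 of 16 tested members. Csf1r, the receptor for colony stimulating factor, measured 120 ± 47.1 (SD, n = 3) against 589 ± 136 (5.04-fold, adjusted p = 0.0021). The receptor genes P2ry12, Cx3cr1 and Gpr34 were 13.6-fold, 8.74-fold and 7.03-fold lower, with TRAP values under 50, and 2.02-fold, 2.82-fold and 1.16-fold lower with values under 50 raised to 50. The list median was -1.85, or -1.03 with values under 50 raised to 50 (camera adjusted p = 0.014, and adjusted p = 0.442 with an estimated correlation). The list lost its call when both group means had to reach 50 (adjusted p = 0.24).

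Astrocyte markers divided. Of 21 tested members 14 were lower and 3 were higher, namely Gjb6, Aldh1l1 and S100b. Aqp4, the water channel of astrocyte endfeet, was 15.0-fold lower (log2 -3.91, SE 0.26, adjusted p = 1.5e-04), Gfap 19.6-fold (7.66-fold with values under 50 raised to 50) and Mlc1 9.46-fold lower. Gjb6, which encodes a connexin, was 5.75-fold higher at 4691 ± 64.9 (SD, n = 3) against 846 ± 257 (adjusted p = 5.9e-04). The list did not pass (median -1.31, camera adjusted p = 0.073), but it passed after centring (adjusted p = 0.0099) and without TRAP replicate 2 (adjusted p = 0.030).

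Markers of other neurons were lower. Of 18 GABAergic interneuron markers 15 were lower and 0 higher, with a median of -1.50 (camera adjusted p = 0.0026). Pvalb, the calcium buffer of fast-spiking interneurons, measured 324 ± 31.5 (SD, n = 3) against 2240 ± 299 (6.89-fold, adjusted p = 3.4e-05). The neuropeptide genes Tac1 and Vip were 6.33-fold and 5.15-fold lower and Reln, which encodes reelin, 4.74-fold lower. Of 10 striatal projection neuron markers 9 were lower, with a median of -1.48 (camera adjusted p = 0.014). The dopamine receptor gene Drd1 was 6.49-fold lower, the opioid peptide genes Pdyn and Penk 7.52-fold and 3.66-fold, and Rgs9 4.82-fold. Pdyn was 1.77-fold lower with values under 50 raised to 50. Both lists had adjusted p = 0.442 with an estimated correlation, and the striatal list lost its call on probe sets without repeated values (adjusted p = 0.18). Counts adjusted over the list alone matched those over all genes for these lists and for the oligodendrocyte and precursor lists, while the astrocyte count became 15 lower and the microglial list gained 1 higher.

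**Figure D2:**
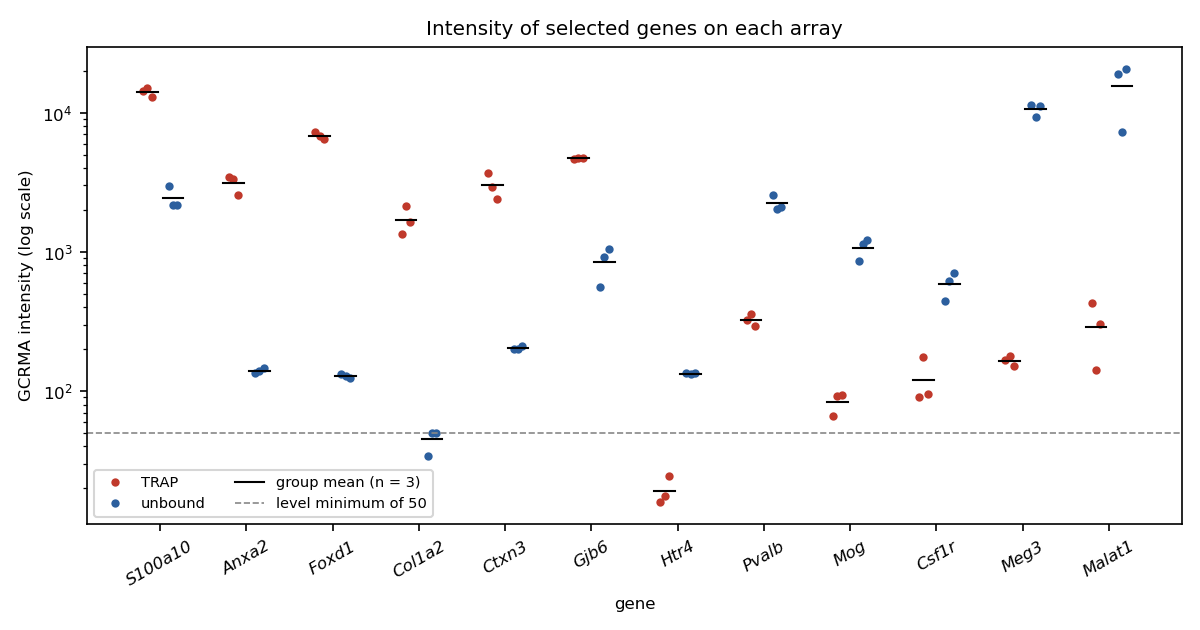
GCRMA intensity, on a log scale, of 12 genes on each of the 6 arrays, with the mean of each group of 3 as a bar. TRAP values lie above unbound values for the 6 genes from S100a10 to Gjb6 and below them for the 6 from Htr4 to Malat1, and the dashed line marks an intensity of 50.

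General markers of glutamatergic pyramidal neurons, the class the labels name as the target, went both ways and were not called by camera as a list. Of 20 tested members 4 were higher and 8 lower, and Camk2a was the only one past 2-fold (2.84-fold lower, adjusted p = 0.0092). The kinase gene Ptk2b, the transcription factor gene Tbr1 and the adhesion gene Icam5 were 1.89-fold, 1.72-fold and 1.63-fold lower. Icam5 lost its call after centring (adjusted p = 0.087) and without TRAP replicate 1 or 2 or unbound replicate 2 or 3 (adjusted p from 0.076 to 0.11). The list median of -0.19 lay close to that of all genes, and the camera direction was upward (adjusted p = 0.63). By fry, which tests against no change, the list was called lower (fry adjusted p = 0.012). After centring the median was 0.02, with 8 members higher and 4 lower. On the same arrays the meningeal list had a median of 3.83 and the oligodendrocyte list one of -2.92.

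The lists for layers 2/3 and 4 were called in opposite directions, and the difference between them was not tested. Layer 2/3 markers were lower in 12 of 14 tested members (median -0.88, camera adjusted p = 0.014). Epha3, an ephrin receptor, was 4.18-fold lower, Wfs1 3.52-fold, Inhba 3.30-fold and Stard8 3.12-fold. Layer 4 markers were higher in 5 of 8 (median 0.61, camera adjusted p = 0.017), led by Ctxn3 at 3008 ± 646 (SD, n = 3) against 204 ± 5.47 (14.5-fold, adjusted p = 2.9e-05), with Cyp39a1 2.61-fold and the channel gene Kcnh5 2.59-fold higher. Whrn was 1.66-fold lower, a call lost when values under 50 were raised to 50. Both lists had adjusted p = 0.442 with an estimated correlation and lost their calls on probe sets without repeated values (adjusted p = 0.11 and 0.078).

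Deeper layers gave no call by camera in the main analysis. By fry each of these lists was called lower. The fry adjusted p was 7.5e-04 for layer 5a, 3.6e-05 for layer 5b and 4.8e-05 for layer 6 and subplate markers. Of 8 markers of layer 5 intratelencephalic neurons (5a), 3 were higher and 4 lower, with a median of -0.15, a mean of -0.43 and an upward camera direction (adjusted p = 0.85). Hsd11b1 was 1.84-fold higher, while Pde1c was 5.06-fold, the channel gene Kcnn2 3.50-fold and Tcerg1l 2.44-fold lower. Pde1c was 1.86-fold lower with values under 50 raised to 50. Median centring turned the list median to 0.06, and on probe sets without repeated values it was 0.70 (adjusted p = 0.022). That filter excluded the probe sets of the 4 lower members, which hold repeated values, so the 0.70 rests on the members left. Of 13 markers of layer 5 subcerebral neurons (5b), 9 were lower and 3 higher (median -0.95, adjusted p = 0.18, or 0.018 on probe sets without repeated values), with Bcl11b, a transcription factor of corticospinal neurons, falling from 6730 ± 455 (SD, n = 3) to 1650 ± 387 (4.14-fold). Colgalt2 was 6.25-fold lower, or 1.40-fold with the raised values, Parm1 3.05-fold and the neurofilament gene Nefh 2.73-fold lower. The probe sets of the 3 higher 5b members, Fezf2, Pcp4 and Slco2a1, hold repeated values and do not enter the 0.018. Some lower members, such as Colgalt2 and Parm1, hold repeated values too. Layer 6 and subplate markers were lower in 11 of 14 (median -1.01, adjusted p = 0.073, or 0.027 after centring with 7 lower), including Cplx3 (3.98-fold), Sla (3.38-fold), Tle4 (3.12-fold) and Car12 (2.66-fold). Counts adjusted over the list alone were unchanged for these layer lists and the pyramidal list.

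Of 8 serotonin receptor genes tested, 6 were lower and 0 higher, and the list did not pass (median -0.67, camera adjusted p = 0.11). Htr4, whose receptor binds S100a10 protein, measured 19.3 ± 4.61 (SD, n = 3) against 133 ± 0.867 (7.04-fold, or 2.67-fold with values under 50 raised to 50, adjusted p = 1.0e-04). The other Htr4 probe set lay under 50 in both groups, at 10.1 against 20.4 (2.02-fold lower). Htr1b, another receptor that binds S100a10 protein, was 1.84-fold lower (adjusted p = 0.0010). Htr1a, Htr1d, Htr5a and Htr7 were 1.82-fold, 1.97-fold (1.32-fold with the raised values), 1.38-fold and 1.39-fold lower, and quantile normalisation ended the calls of Htr5a (log2 -0.19) and Htr7 (log2 -0.22). Htr2c (log2 -0.48, adjusted p = 0.080) and Htr1f (log2 0.50, adjusted p = 0.14) were not called. Htr1f depended on the probe set, with -0.58 for the mean of its probe sets and -1.65 on probe sets without repeated values, and it was called higher without TRAP replicate 2 (0.77), after centring (0.71) and after quantile normalisation (0.81), as Htr2c was called lower without TRAP replicate 3 (-0.68).

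Transcripts for receptors and ion channels were mostly lower. GABA-A receptor subunits were lower in 9 of 9 tested (median -1.07, camera adjusted p = 0.017), with Gabra3 4.44-fold, Gabrg1 3.50-fold, Gabra2 2.84-fold and Gabrb1 2.51-fold lower. Of 20 glutamate receptor genes 16 were lower and 1, Grm2, was higher (median -1.05, adjusted p = 0.014). Gria3, an AMPA receptor subunit, fell from 8380 ± 628 (SD, n = 3) to 2299 ± 302 (3.66-fold, adjusted p = 1.2e-04), Gria1 was 3.83-fold, Grik3 3.63-fold and the NMDA receptor gene Grin2c 7.46-fold lower, or 3.60-fold with values under 50 raised to 50. Sodium, calcium and HCN channel genes were lower in 18 of 25 (median -0.84, adjusted p = 0.014), among them Scn3a (3.97-fold), Cacna1h (3.38-fold), Scn4b (3.23-fold) and Cacna1d (2.86-fold). Of 37 potassium channel genes 28 were lower and 3 higher (median -0.64, adjusted p = 0.023), with Kcna5, Kcna1 and Kcnip1 3.61-fold, 3.32-fold and 3.06-fold lower. Other neuromodulator receptors were lower in 15 of 21 (median -0.60, adjusted p = 0.031), with Drd2, Oxtr and Npy2r 2.92-fold, 2.87-fold and 2.53-fold lower (2.16-fold, 1.96-fold and 1.71-fold with the raised values), and 2, Crhr1 and Tacr3, were higher. With an estimated correlation the adjusted p was 0.442 for the GABA-A and the sodium, calcium and HCN lists, 0.481 for neuromodulator receptors and 0.546 for glutamate receptors and potassium channels. The neuromodulator list also lost its call with no filter, with a minimum of 100, with both means at 50 and for the mean of probe sets (adjusted p from 0.050 to 0.086), and on probe sets without repeated values (adjusted p = 0.52). The potassium channel list lost it for the mean of probe sets (adjusted p = 0.051). Leaving out unbound replicate 2 ended the calls of the potassium channel and neuromodulator lists (adjusted p = 0.053 each).

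Axon guidance genes were lower in 34 of 47 tested (median -0.69, camera adjusted p = 0.0048, and adjusted p = 0.546 with an estimated correlation). The semaphorin gene Sema3e was 6.49-fold lower, at 123 ± 24.9 (SD, n = 3) against 791 ± 77.5, and Ntng2, a netrin relative, was 5.01-fold lower, or 1.27-fold with values under 50 raised to 50. One member, Sema3d, was higher at a log2 fold change of 1.85. Of 31 synaptic vesicle genes 17 were lower and Stx1a was higher (median -0.31, adjusted p = 0.073), with a call gained when replicate numbers entered as a block (adjusted p = 0.022) and without TRAP replicate 3 or unbound replicate 1 (adjusted p = 0.049 and 0.022). After centring the vesicle count was 10 lower and 4 higher, with a median of -0.10. Syt2, Doc2b and Cplx2, which act in vesicle fusion, were 2.79-fold, 2.58-fold and 2.54-fold lower, and Rab3c was 2.30-fold lower, or 0.012 on the log2 scale for the mean of its probe sets. Counts adjusted over the list alone were unchanged for the receptor, channel, guidance and vesicle lists. On these arrays the markers of oligodendrocytes, microglia and interneurons were lower too, with medians of -2.92, -1.85 and -1.50.

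Nuclear long noncoding RNAs were lower in 12 of 12 tested (median -2.36, camera adjusted p = 0.0010, and adjusted p = 0.442 with an estimated correlation), also when adjusted over the list alone. Meg3, an imprinted transcript, fell from 10579 ± 1042 (SD, n = 3) to 166 ± 13.1 (63.8-fold, adjusted p = 2.1e-06). Malat1, a speckle-associated transcript, was 53.5-fold lower with a wide spread (SE 0.60, adjusted p = 7.2e-04), Miat 37.3-fold and Snhg11 19.9-fold. Mir124a-1hg, the host transcript of a neuronal microRNA, was 83.4-fold lower, or 15.6-fold with values under 50 raised to 50. The control probe set for the B1 repeat, a short interspersed element found in many nuclear transcripts, measured 1425 ± 123 against 24749 ± 1667 (SD, n = 3), 17.4-fold lower (adjusted p = 2.8e-06), while the control for another such element, B2, was 1.34-fold lower at 31419 against 42132 (adjusted p = 1.9e-04). Other genes among the largest decreases were Tet2, a DNA demethylation enzyme (59.2-fold, or 7.67-fold with the raised values), the zinc finger genes Zfp950 (50.5-fold, or 11.4-fold) and Zfp40 (31.2-fold, or 4.85-fold), Cfp, the complement factor properdin (21.8-fold, or 7.52-fold), and Vcan, the proteoglycan versican (19.6-fold, or 2.44-fold).

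The single mitochondrially encoded gene tested, ND5, a subunit of respiratory complex I, showed the largest decrease, from 13894 ± 4657 (SD, n = 3) to 25 ± 0.134 (533-fold, or 266-fold with values under 50 raised to 50, adjusted p = 1.1e-05). Mitochondrial ribosomes translate mitochondrially encoded mRNA, and TRAP recovers mRNA on tagged ribosomes, so this decrease need not measure expression in the labelled cells. Nuclear-encoded oxidative phosphorylation genes were higher in 40 of 58 and lower in 5 (median 0.39, camera adjusted p = 1.3e-08, and adjusted p = 0.442 with an estimated correlation). Their changes were small: Ndufs5 was 2.02-fold, Atp5e 1.91-fold and Atp5d 1.88-fold higher. Cox7c was 11.2-fold lower on a probe set of low intensity, or 1.66-fold with the raised values, and lost its call when values under 50 were raised to 50. Cytosolic ribosomal protein genes were higher in 10 of 40 and lower in 5 (median 0.10, adjusted p = 0.016, and adjusted p = 0.611 with an estimated correlation), or 5 and 4 adjusted over the list alone. After centring 23 were higher and 3 lower, with a median of 0.31. Rps10 was 1.74-fold and Rplp2 1.57-fold higher, Rps19 1.83-fold and Rps25 1.67-fold lower. The ribosomal list lost its call with no filter on low values (adjusted p = 0.097) and after quantile normalisation (adjusted p = 0.062), and it did not pass by fry (fry adjusted p = 0.68). Rps10 was not called without any 1 of the 3 TRAP arrays or without unbound replicate 2 or 3, and Rps25 without TRAP replicate 1 or 3 (adjusted p from 0.052 to 0.10).

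Immediate early genes, which neuronal activity induces, varied between arrays of a group, and 5 of 19 were lower and 0 higher (median -0.02, camera adjusted p = 0.68). Fosb was 2.03-fold, Bdnf 1.98-fold, Nptx2 1.62-fold and Fosl2 1.57-fold lower. The count adjusted over the list alone was 0, and centring turned the list median to 0.19, with 3 lower and 2 higher. Single arrays decided 3 of these calls, with adjusted p from 0.052 to 0.080 once lost. Fosb lost its call without unbound replicate 1 or 2, Fosl2 without these or TRAP replicate 2, and Nptx2 without TRAP replicate 3 or any 1 unbound array. Nptx2 also lost it after centring (adjusted p = 0.053) and after quantile normalisation (adjusted p = 0.079).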

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

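The tests of RNA carry-over and of both explanations for repeated values were chosen after the result was seen.

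Signal appeared in probe sets that the comparisons of genes do not use. The control probe sets for the 5′ and middle parts of 18S ribosomal RNA were higher in TRAP RNA, with log2 fold changes of 0.37 (adjusted p = 0.0050) and 0.59 (adjusted p = 0.0059), and the control for the 3′ part of the actin transcript was higher by 0.20 (adjusted p = 0.0067). The controls for the 3′ part of 18S (0.17), the 5′ part of actin (0.21) and both parts of Gapdh (3′ -0.057, 5′ -0.013) were not called (adjusted p from 0.11 to 0.91). These adjusted p-values are from limma over all probe sets that passed the level minimum. The 3 TRAP values lay above the 3 unbound values for each of the 3 controls. The groups also did not overlap, in either direction, for 75.5% of all genes tested, so this separation adds little. Of 1763 probe sets without a gene name that passed the level minimum, 70 were at least 2-fold higher and 649 at least 2-fold lower. Actin 3′ to 5′ intensity ratios were 4.34 ± 0.585 (SD, n = 3) in TRAP RNA and 4.35 ± 0.211 in unbound RNA.

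Meningeal fibroblast genes were higher in TRAP RNA, and 14 of 15 passed the test against a 2-fold change. Inflation by unbound values near background is argued against by the list median of 3.79 with values under 50 raised to 50, and 12 of the 15 genes reached 50 in unbound RNA. Carry-over of RNA from unlabelled cells stays open where it favours some cells: the oligodendrocyte and microglia medians of -2.92 and -1.85 do not decide it, since carry-over of whole cortex RNA moves folds towards 0. Another candidate explanation is expression of the tagged ribosomal protein in meningeal or related non-neuronal cells, which the series text mentions for this line and which no test here addressed. The members with the highest intensities, which probe affinity also sets, were Ptgds, at 31978 ± 807 (SD, n = 3) against 7805 ± 1630, and Fmod, at 12747 ± 2570 against 483 ± 120; 0 of the 15 are in another list.

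Nuclear noncoding RNAs were lower in TRAP RNA in 12 of 12 tested. A trend of the fold with expression level is argued against, since the list median of -2.36 lay at percentile 0 among 10000 random lists matched on mean level. If the unbound RNA held more transcripts that are not on ribosomes, probe sets without a gene name would be lower too, and their median lay 0.36 below that of named probe sets of matched level (difference -0.36; -0.67 against -0.31, with matched draws from -0.35 to -0.26). This is consistent with nuclear or unspliced RNA in the unbound fraction, as a hypothesis, while the controls for short repeats were lower by unequal amounts, B1 17.4-fold and B2 1.34-fold. Noncoding RNA that the labelled cells themselves express less stays open and was not tested.

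Repeated values on arrays of one group bear on each small fold. The deposit of 1 array in several columns is argued against, since 0 of 18 hybridisation control probe sets held a repeated value. Among 2546 probe sets whose group means differed by under 0.1 log2, 17.4% of values were identical on pairs within a group and 0% between groups. The lowest intensity was 1.73 on each TRAP array and 1.63 on each unbound array. In the simulation of median polish, all 6 arrays together gave 0% identical values within a group. These values argue against 1 run of all 6 arrays and go with each group having been processed apart. In that case part of the median shift of -0.21 and of the small differences may come from the processing, and scaling cannot remove a shift particular to a probe set. No biological explanation was tested.

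With 6 arrays there are 10 splits into 3 and 3, too few for a share under 0.05, and that is all the counts can say about chance. The real split gave 2812 genes higher, 5517 lower, 880 at least 2-fold higher and 1608 at least 2-fold lower, and for each of these counts it was the 1 split of 10 to reach that value, the highest of the other splits being 0 by limma, with 2 to 212 genes at an unadjusted p under 0.05 against 8712 in the real split. For gene lists, counting either direction of a split, 8 of 10 splits gave at least the 6 lists higher in TRAP and 4 of 10 at least the 12 lower, and the highest other count was 14. If replicate numbers pair the samples, 3 other splits also part all 3 pairs. Those splits gave 0 genes and at most 13 lists in one direction. Splits that mix the groups keep part of the real difference between lists.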

How the results depend on the processing

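The alternatives without _s_at and _x_at probe sets, without repeated values and against a 2-fold change were chosen after the data were seen. S100a10 was higher in TRAP RNA under each alternative fitted with 1 value per gene, with log2 fold changes from 2.48 without unbound replicate 3 to 2.70 without unbound replicate 1 when single arrays were left out, and 2.66 after quantile normalisation. With no filter 4797 genes were higher and 8354 lower, and with each probe set on its own 4663 and 10767 (1394 and 3747 at 2-fold), since more features were tested. Requiring 50 in both groups left 528 genes 2-fold higher; 356 of the 880 have an unbound mean under 50 and 387 of the 1608 a TRAP mean under 50, where background limits the fold. Quantile normalisation gave 1050 genes 2-fold lower and 1256 higher, and centring 1112 and 1199, so the balance turned; quantile normalisation moved the median of all genes from -0.21 to 0.0037. Probe sets without repeated values gave 1372 higher and 2734 lower (383 and 881 at 2-fold) among 6975 genes, and the test against a 2-fold change 547 and 792. With single arrays left out, counts ranged from 2440 to 2818 higher, 4863 to 5201 lower, 847 to 939 at 2-fold higher, 1549 to 1663 at 2-fold lower, 6 to 6 lists higher and 10 to 14 lists lower. Lists higher and lower numbered 4 and 16 after quantile normalisation, 5 and 15 after centring, 4 and 12 with no filter, 5 and 10 with both means at 50, 8 and 12 with a minimum of 100, and 6 and 10 for the mean of probe sets. With an estimated correlation 0 lists were higher and 0 lower. Fry, which tests against no change, gave 6 higher and 20 lower. It called the endothelial and the choroid plexus lists higher (fry adjusted p = 2.8e-05 each), but not the pericyte (0.53) and cytosolic ribosomal (0.68) lists. Among those lower by fry but not called by camera were the layer 5b, layer 6, astrocyte, precursor, serotonin receptor and synaptic vesicle lists. By fry the pyramidal (-0.19) and layer 5a (-0.15) lists were called lower (fry adjusted p = 0.012 and 7.5e-04). Their direction was opposite to that of camera, which tests against other genes and did not call them. Htr1f turned to -0.58 for the mean of its probe sets and -1.65 without repeated values, and Rab3c to 0.012 for the mean. These values draw on other probe sets of the genes, which went the other way from the main one. Why the probe sets differ was not tested. With replicate numbers as a block 8789 genes were called, 8078 of them among the 8329. Of the lists, the synaptic vesicle list alone changed its call with the block (-0.31, camera adjusted p = 0.022). Over the alternatives its adjusted p ran from 0.0014 by fry to 0.57 by camera with an estimated correlation. Of the other comparisons with an alternative, 2318 for named genes kept direction and side of the threshold, 74 lost the call and 4 gained it; for lists these were 509, 38 and 29.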

Other observations

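The gene families and the comparisons of layer 5a with other layers were chosen after the data were seen.

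Of 14 gene families outside the fixed lists, 8 passed camera and 0 passed with an estimated correlation (adjusted p from 0.539 to 0.868). Of 76 genes for mitochondrial ribosomal proteins, which translate mitochondrially encoded mRNA, 61 were higher and 4 lower in TRAP RNA (median log2 fold change 0.61, camera adjusted p = 6.4e-13). Mrpl14 was 2.86-fold and Mrpl36 2.40-fold higher. Of 38 proteasome subunit genes 21 were higher and 4 lower (median 0.27, adjusted p = 3.2e-05), led by the immunoproteasome genes Psmb8 (4.51-fold) and Psmb9 (2.25-fold). Glutathione transferases, enzymes of detoxification, were higher in 11 of 15 (median 0.92, adjusted p = 8.3e-05), with Gstt2 19.9-fold (6.76-fold with values under 50 raised to 50) and Gstt1 6.14-fold higher. Collagens were higher in 10 and lower in 6 of 20 (median 0.62, adjusted p = 0.034), and insulin-like growth factor binding proteins higher in 3 and lower in 1 of 6 (median 0.68, adjusted p = 0.032). Meningeal fibroblast markers were higher in the same samples (list median 3.83), and Col1a2, Col3a1 and Igfbp2 belong to that list too.

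Other families were lower. Zinc finger genes with Zfp symbols were lower in 173 and higher in 36 of 296 (median -0.37, camera adjusted p = 0.014). Protocadherins, adhesion molecules of neurons, were lower in 18 of 21 (median -0.69, adjusted p = 0.011), with Pcdh11x 6.15-fold and Pcdh17 3.98-fold lower. After centring 11 protocadherins were lower and 1 higher, with a median of -0.48. Interneuron markers were lower in the same samples (list median -1.50), the oligodendrocyte precursor list had a median of -1.95 without passing, and Pcdh15 belongs to the precursor list too. Lysine demethylases and methyltransferases, which modify histones, were lower in 18 of 25 (median -0.62, adjusted p = 0.016), with Kmt2a 4.73-fold lower. After centring 12 of them were lower and 1 higher. Centring the arrays, which removes the shift of all genes of -0.21, left the sign of each of the 8 medians as it was, with the smallest, that of the Zfp genes, at -0.16 (130 lower and 60 higher). Solute carriers, tubulins, keratins, DEAD-box helicases, vacuolar ATPase subunits and splicing factors did not pass (adjusted p from 0.18 to 0.78).

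One hypothesis was that markers of layer 5 intratelencephalic neurons (5a) were more enriched than markers of other layers. The mean log2 fold change of the 8 tested 5a genes was -0.43, which lay 0.56 above that of layer 2/3, 0.51 above layer 5 subcerebral and 0.36 above layer 6 markers, and -1.33 from that of layer 4 markers. Exact two-sided permutation tests over genes, adjusted over the 4 comparisons, gave adjusted p = 0.38, 0.38, 0.43 and 0.24, so none of the 4 differences passed. The lists hold 8 to 14 genes each, genes are not independent replicates, and the tests leave open a difference of this size.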
